A study of Danio rerio with 16 samples.

How the data were processed

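RNA of whole zebrafish larvae was measured on 16 two-colour Agilent arrays, 4 groups of 4 samples, each sample being a pool of 20 larvae from 1 of 4 independent experiments. Groups and replicate numbers were taken from the sample titles, and the replicate number is the experiment. The labels state that each sample was hybridised with a common reference of all RNA samples and that dyes were not swapped, with Cy5 for the sample and Cy3 for the reference. Each experiment was on its own slide and the slides were scanned on 1 day, per the file headers, so that experiment and slide are the same split. Every group had the same position on each slide, so that position and group cannot be told apart.

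The deposited scanner tables hold spot intensities (mean brightness and median local background of each spot per channel), which Agilent Feature Extraction read from the scan, version 10.7.3.1 per the file headers, while the submitters' processing notes list 9.5.3.1 and 9.5. The same tables hold processed intensities, which Feature Extraction had background-corrected and dye-normalised within each array per the file headers. The deposited series value table holds an error score per spot, which Feature Extraction computed as the error of the log10 ratio, per the file headers, and it was not used as expression. Its values equal that error for all 175974 probes of every array within a relative difference of 0.005, and their correlation with the log10 ratio was at most 0.02 on any array. The column medians lie between 0.0642 and 0.0676, and the values carry no centring and no direction. Of 180822 spots per array, 4848 were controls. No probe had a gene name: the gene columns of the scanner tables repeat the probe identifier, and the separate reference tables hold neither probe identifiers nor probe sequences. The test of gene lists, the gene lists themselves and the summary by gene that had been planned were therefore not run.

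From the mean and background intensities, the background was corrected with normexp (offset 50), the log ratio was normalised by loess within each array with control spots and outlier-flagged spots at weight 0, control spots were removed and outlier-flagged spots (38 to 215 per array) were set to missing. Probes were kept where Cy5 was well above background on all 4 arrays of at least 1 group, which left 136712 and removed 39262. Each probe was printed once per array. Median intensities were 184.7 to 212.2 in Cy3 and 274.9 to 305.8 in Cy5, against median local backgrounds of 37 to 52 and 48 to 55.

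The planned ratio was log2(Cy5/Cy3), after the labels. Single-channel fits and the limit that a pool of all samples sets to the mean ratio showed that Cy3 follows the treatment, and the sign was turned to log2(Cy3/Cy5) after the data were seen. This changes no count, size or p-value. The planned filter on Cy5 was kept, and the same filter on Cy3, which keeps 140640 probes, was added as an alternative. All named probes were well above background in Cy3 on at least 3 of 4 arrays of every group.

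A linear model with 4 group means over all 16 arrays was fitted per probe with limma 3.58.1 in R 4.3.3, with moderated variances (prior degrees of freedom 4.07) and Benjamini-Hochberg adjustment over the tested probes within each comparison. A missing spot left only its own array out of that probe's fit, the test is two-sided, and a probe passed at an adjusted p below 0.05 with no fold limit. The 7 comparisons were beclomethasone against vehicle in each genotype and over both, GRβ against wild type under each treatment and over both, and the interaction. The response score and its exact permutation test were defined before the data were examined, as were the comparisons, filters and alternatives, except those said to be added.

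The planned rule for named genes (the largest rises and falls that pass with non-overlapping groups, and the receptor and construct genes in every comparison) was applied to probes, because genes could not be named, and its part on the receptor and construct genes could not be applied. The response score, planned over 1 probe per gene, was likewise taken over all response probes. At most 2 probes that rose and 2 that fell are named per comparison, from different families of probes with identical or end-to-end overlapping sequences (at least 25 bases), and the 2 probes with the smallest p where none passed. Of the 175974 probes, 25090 belong to 10483 families of 2 or more, and cross-hybridisation between related transcripts cannot be excluded without a reference. LOL03940, the second probe of the family of LOL03948, was higher by 1.59 log2 units over both treatments. Both have the same sequence, so their agreement says nothing about cross-hybridisation.

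Replicate numbers paired the samples: the labels give 4 independent experiments, and the deviations from the group means correlated above 0.1 in 24 of 24 pairs of arrays with one number (0.16 to 0.76, median 0.57). The median was -0.23 for 72 pairs with different numbers. Deviations cancel within a group, so positive correlations for one number force negative ones for different numbers. The -0.23 is therefore no separate evidence of pairing. The fit with the experiment as a block (prior degrees of freedom 6.04) is given beside each count of passing probes that it moved by more than 1.5 times. The alternatives were no background correction, Feature Extraction's processed intensities, median centring in place of loess, quantile normalisation between arrays, no filter, the block, an intensity trend with robust prior, a limit of 1.5-fold, only the groups compared, and each array left out, and as additions after seeing the data the filter on Cy3, Cy3 alone and means per probe family.

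The fitting code was tested on simulated data: its statistics equalled those of limma's own functions, and in 136040 simulated probes with the real spread 86.6% of 2-fold and 31.3% of 1.5-fold changes were recovered for beclomethasone in wild type and 95.5% and 64.2% for GRβ over both treatments. The simulated noise was independent between arrays. These shares need not hold for the real arrays, which share differences between experiments.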

Results

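Gene expression was measured in whole zebrafish larvae that either were wild type or carried Tg(hsp70:Gal4, UAS:EGFP-grbeta), a construct from which heat shock drives a GFP-tagged beta isoform of the glucocorticoid receptor (GRβ). The glucocorticoid receptor is the transcription factor through which glucocorticoids act, and beclomethasone is a synthetic glucocorticoid. All larvae received a heat shock of 2.5 h at 37 °C at 1 and again at 2 days post fertilisation, and at 3 days they were exposed for 6 h to 25 µM beclomethasone or to the vehicle, 0.05% DMSO. This gave 4 groups, namely wild type with vehicle, wild type with beclomethasone, GRβ with vehicle and GRβ with beclomethasone. Each group was sampled in 4 independent experiments, with RNA of 20 larvae pooled per sample, so that 16 samples were hybridised, each with a common reference made of RNA of all samples, to 16 two-colour arrays. Each experiment filled 1 slide.

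Each array carried 175974 probes of 60 bases. Between 77.2% and 83.4% of the probes per array were well above background in Cy3 and between 73.7% and 81.2% in Cy5, no spot was saturated, and 136712 probes were kept, of which 136691 could be tested. The number of arrays limits the precision, and the median standard error of a difference between 2 groups was 0.126 on the log2 scale. The files give each probe an identifier and a sequence but pair no probe with a gene, so that probes are reported here by identifier, sequence and value, and neither the construct's transcript nor any gene list could be looked up by name.

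The direction of the ratios was taken from the signals. The labels assign the larval RNA to Cy5 and the reference to Cy3, but the differences under beclomethasone lay in Cy3: with Cy3 signals alone, 13237 probes passed an adjusted p of 0.05 (limma) for beclomethasone against vehicle over both genotypes, and with Cy5 signals alone 3 probes did. The counts were small in both channels for GRβ under vehicle (0 in Cy3 and 7 in Cy5) and for the interaction (0 and 4). They were also small for GRβ under beclomethasone (16 and 0) and for GRβ over both treatments (36 and 0). A reference that pools all samples also limits the mean ratio of sample to reference over the 16 arrays to about 1, apart from any dye bias at single probes. The mean linear Cy5/Cy3 ratio exceeded 2 for 511 probes and reached 11.7, whereas no probe had a mean Cy3/Cy5 ratio above 2 and the highest was 1.65. Values are therefore log2(Cy3/Cy5), read as larvae over reference. This opposes the dyes in the labels, under which the sign of every probe's ratio and difference, and every rise and fall of probes, would turn. Counts, sizes, p-values and correlations would stay. So would the response score described below, because it is signed by the direction of the response itself.

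The first comparison asked how wild type larvae respond to the glucocorticoid. Beclomethasone raised 3409 probes and lowered 2367 in wild type larvae, 4.23% of the 136691 probes tested (limma, 4 against 4 arrays, adjusted p below 0.05). Large changes were mostly rises: 818 probes rose and 149 fell at least 2-fold, and 111 rose and 4 fell at least 4-fold. The largest rise in this fit was that of probe MAD_Dr_004_163333-1 (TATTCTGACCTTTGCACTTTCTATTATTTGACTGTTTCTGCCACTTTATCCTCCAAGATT), whose log2 ratio to the reference was -4.03 ± 0.36 (SD, n = 4) under vehicle and 0.86 ± 0.41 (SD, n = 4) under beclomethasone. Its difference was 4.90 log2 units (SE 0.24, limma adjusted p = 1.72e-08), a 29.8-fold rise, and lay between 4.43 and 5.53 within the 4 experiments. Probe MAD_Dr_004_157486-1 (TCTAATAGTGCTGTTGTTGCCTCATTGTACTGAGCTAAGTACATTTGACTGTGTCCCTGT) rose by 4.33 log2 units (SE 0.26, limma adjusted p = 6.87e-08), from -3.33 ± 0.32 to 1.01 ± 0.42 (SD, n = 4 each). The largest falls were those of MAD_Dr_004_196898-1 (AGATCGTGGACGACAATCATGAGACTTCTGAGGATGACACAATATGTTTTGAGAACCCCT), with a difference of -2.48 log2 units (SE 0.37, limma adjusted p = 0.000558), and of MAD_Dr_004_158535-1 (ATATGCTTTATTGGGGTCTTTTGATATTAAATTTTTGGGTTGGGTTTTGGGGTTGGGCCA), with a difference of -2.33 (SE 0.28, limma adjusted p = 6.96e-05). Sizes and their order depended on the processing of the intensities. Without background correction the order of the rises stayed, with 5.02 for MAD_Dr_004_163333-1 and 4.52 for MAD_Dr_004_157486-1. With Feature Extraction's processed intensities, MAD_Dr_004_157486-1 rose by 5.78 and MAD_Dr_004_163333-1 by 5.61, so that their order turned, and MAD_Dr_004_196898-1 differed by -3.26. By the rule for naming probes, the 4 arrays of one group all lay above the 4 of the other for each of these 4 probes. Their change in the same direction in 4 of 4 experiments follows from that rule. With the experiment as a block, 7636 probes rose and 7044 fell.

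**Figure D1:**
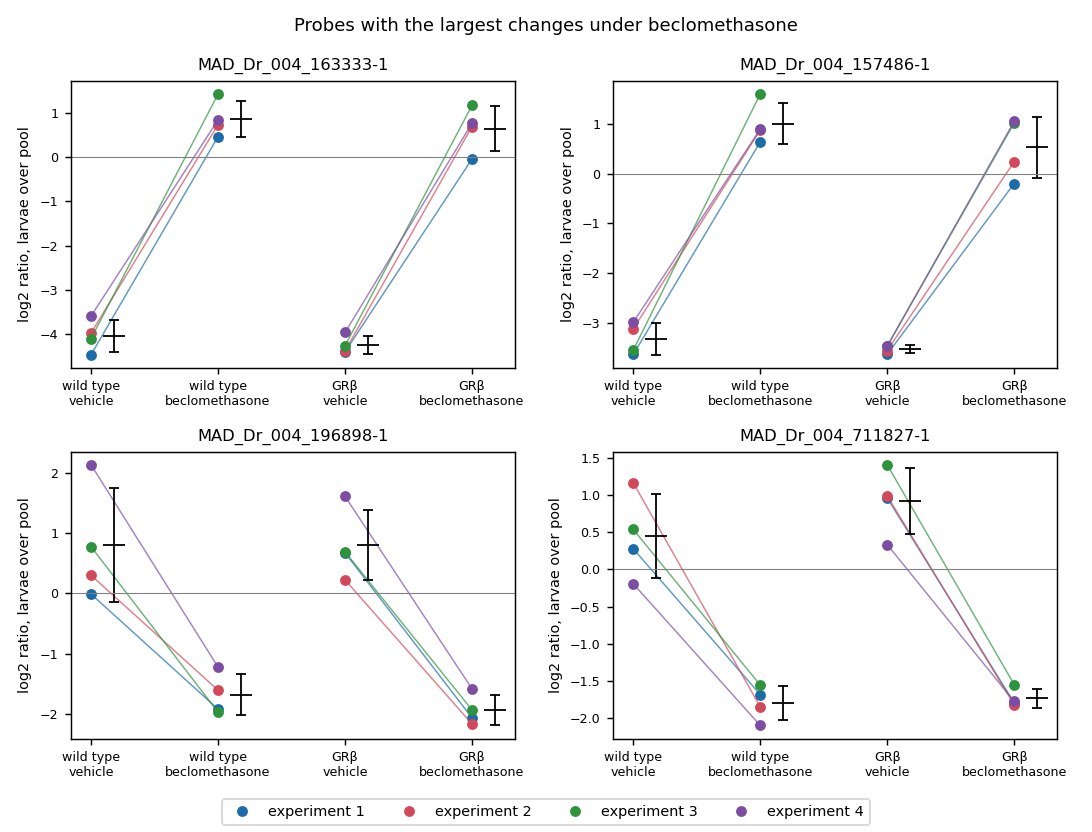
Log2 ratio of larvae over the common reference (y axis) in the 4 groups (x axis) for the 2 probes with the largest rise and the 2 with the largest fall under beclomethasone over both genotypes. Points are arrays coloured by experiment, and lines join the vehicle and beclomethasone arrays of one genotype and experiment. Bars give the mean ± SD of 4 arrays. Every line of a panel runs in the same direction, which the choice of probes with non-overlapping groups fixed. MAD_Dr_004_163333-1 goes from -4.03 to 0.86 in wild type and from -4.25 to 0.64 in GRβ larvae.

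The same treatment was then compared in larvae that carried the GRβ construct. Beclomethasone raised 3333 probes and lowered 2168 in these larvae (limma, 4 against 4 arrays). The same pair of probes led the rises, MAD_Dr_004_163333-1 with 4.90 log2 units (SE 0.24, limma adjusted p = 2.58e-08) and MAD_Dr_004_157486-1 with 4.07 (SE 0.26, limma adjusted p = 1.49e-07). The largest falls were those of MAD_Dr_004_196898-1, by -2.74 (SE 0.37, limma adjusted p = 0.000238), and of MAD_Dr_004_711827-1 (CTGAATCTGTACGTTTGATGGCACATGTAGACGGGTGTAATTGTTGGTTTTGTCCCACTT), by -2.65 (SE 0.24, limma adjusted p = 5.3e-06), each in 4 of 4 experiments. The rule for naming probes, which asks for non-overlapping groups, fixed that agreement beforehand. With the experiment as a block, 7604 probes rose and 6977 fell. Without replicate 3 of the GRβ vehicle group, 3632 probes passed in place of 5501.

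Over both genotypes, 6872 probes rose and 6064 fell under beclomethasone (limma, 8 against 8 arrays), and these 12936 probes are called the response probes below. Of them, 826 rose and 136 fell at least 2-fold, and the median size of change was 0.43 log2 units. MAD_Dr_004_163333-1 rose by 4.90 (SE 0.17, limma adjusted p = 9.08e-11) and MAD_Dr_004_157486-1 by 4.20 (SE 0.18, limma adjusted p = 4.84e-10), and MAD_Dr_004_196898-1 differed by -2.61 (SE 0.26, limma adjusted p = 3.78e-06) and MAD_Dr_004_711827-1 by -2.45 (SE 0.17, limma adjusted p = 7.95e-08). Blocking on the experiment gave 12777 rises and 13694 falls. Both fits count the pairs of one experiment in the different genotypes as independent.

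The responses of the genotypes were close in direction and in size. Of the 5776 probes that passed in wild type larvae, 5757 (99.67%) had the same sign in GRβ larvae, whose arrays are not among those of the wild type comparison. Their mean signed response was 0.75 log2 units in wild type, where they were chosen, and 0.69 in GRβ larvae. Of the 5501 probes that passed in GRβ larvae, the mean signed response was 0.75 there and 0.72 in wild type. In both genotypes 2613 probes rose, where independent lists would share 83.1, and 1607 fell, where independent lists would share 37.5. No probe passed in opposite directions. Across the 136692 probes with a difference in both genotypes the correlation of the responses was 0.816. Across the 12936 response probes, which were chosen on the mean of both responses, it was 0.976, and the slope of the GRβ on the wild type response was 0.956. These values are across probes, which are not independent replicates.

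**Figure D2:**
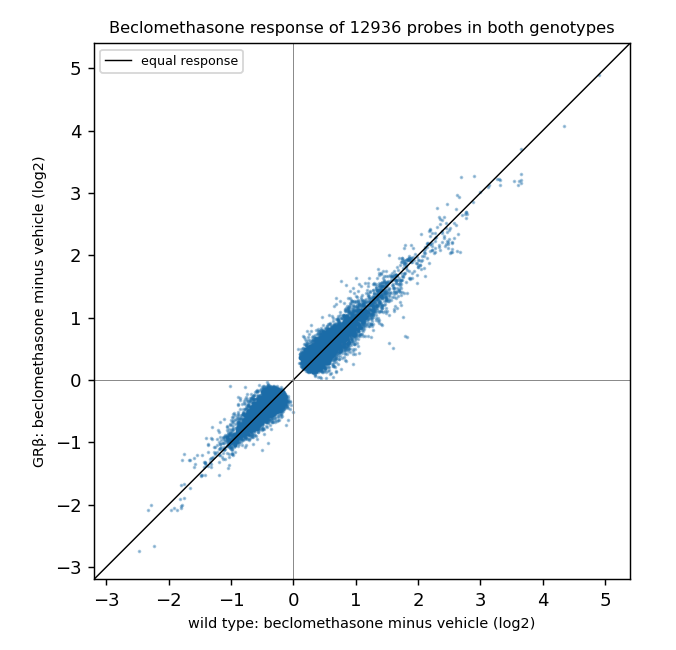
Each point is 1 of the 12936 response probes, with its beclomethasone minus vehicle difference (log2) in wild type larvae on the x axis and in GRβ larvae on the y axis. The points follow the line of equal response (r = 0.976), and the highest point is at 4.90 on both axes.

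Whether the response to the glucocorticoid differs in carriers of the GRβ construct was tested as the interaction of genotype and treatment. No probe passed the interaction test (limma, adjusted p below 0.05), with or without the experiment as a block, and 1380 probes had an unadjusted p below 0.05 without the block and 5111 with it. Both counts lie below the share of 0.05 of the tested probes that chance alone gives on average. The probes with the smallest p, neither of which passed, were MAD_Dr_004_627633-1 (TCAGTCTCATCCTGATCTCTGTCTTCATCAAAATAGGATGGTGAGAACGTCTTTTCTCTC), whose interaction was -0.50 log2 units (SE 0.11, limma adjusted p = 1), and MAD_Dr_004_691088-1 (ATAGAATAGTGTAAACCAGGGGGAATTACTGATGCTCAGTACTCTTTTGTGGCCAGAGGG), with 0.55 (SE 0.13, limma adjusted p = 1). In simulated arrays with the spread of the unblocked fit, which includes the differences between experiments, the unblocked test recovered 90.9% of 4-fold, 56.7% of 2-fold and 7.5% of 1.5-fold interactions. The simulated noise was independent between arrays, so these shares need not hold for the real arrays. Recovery with the block was not simulated.

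Averaging over the response probes gave a more precise comparison. The response score of an array is the mean log2 ratio of the response probes, with the sign turned for those that fell. It rose under beclomethasone by 0.54 ± 0.03 (SD, n = 4 experiments) in wild type and by 0.53 ± 0.06 (SD, n = 4 experiments) in GRβ larvae. The difference between the genotypes was -0.01 log2 units, the ratio of the responses was 0.985, and an exact two-sided permutation test of the 4 against 4 responses gave p = 0.8, where 0.0286 is the smallest p the 70 assignments allow. Within experiments, the GRβ response minus the wild type response lay between -0.08 and 0.04. The ratio was 0.987 for response probes that rose and 0.981 for those that fell (exact permutation p = 0.857 for each). The score itself was -0.27 ± 0.03 under vehicle in GRβ larvae and -0.29 ± 0.05 in wild type larvae (SD, n = 4, exact permutation p = 0.4), and under beclomethasone it was 0.26 ± 0.03 and 0.24 ± 0.03 (SD, n = 4, exact permutation p = 0.371). These permutation tests exchange values freely between the genotypes and do not use the pairing of the genotypes by experiment.

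**Figure D3:**
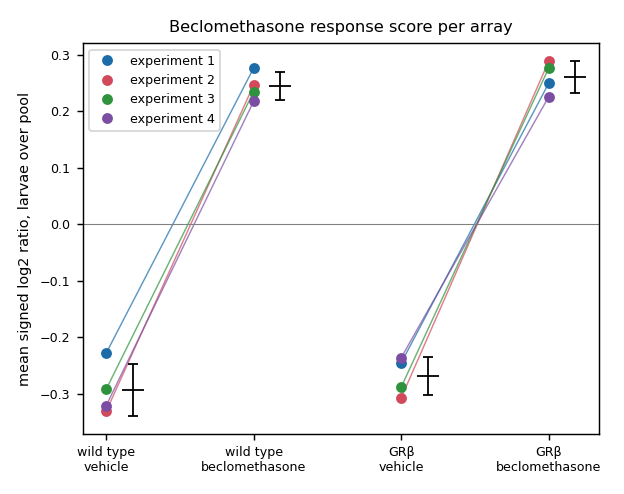
Response score (mean signed log2 ratio over 12936 probes, y axis) of each array in the 4 groups (x axis). Points are arrays coloured by experiment, lines join arrays of one genotype and experiment, and bars give the mean ± SD of 4 arrays; the vehicle scores lie between -0.33 and -0.23 and the beclomethasone scores between 0.22 and 0.29 in both genotypes.

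GRβ larvae were compared with wild type larvae under vehicle to ask how carriers of the construct differ without an added agonist. The only control was wild type. An effect of GRβ therefore cannot be told apart from one of Gal4, EGFP or any other difference between the fish. No probe passed (limma, adjusted p below 0.05), and 2642 probes had an unadjusted p below 0.05 (13011 with the experiment as a block). Chance alone gives an unadjusted p below 0.05 to a share of about 0.05 of the 136691 probes tested. The first count lies below that share and the blocked count above it. The absence of passing probes without the block therefore does not show that no probe differed. The probes with the smallest p were A_15_P101987 (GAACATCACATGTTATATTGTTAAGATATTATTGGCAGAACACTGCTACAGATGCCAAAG), with -0.33 ± 0.04 in GRβ and 0.57 ± 0.27 in wild type larvae (SD, n = 4), and LOL03948 (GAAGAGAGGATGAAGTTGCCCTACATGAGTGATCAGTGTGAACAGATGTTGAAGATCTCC), with 0.45 ± 0.51 and -0.98 ± 0.09 (SD, n = 4). Their limma adjusted p was 0.104 for each. Without replicate 3 of the GRβ vehicle group, 9 probes passed, LOL03948 among them (limma adjusted p = 0.0105). With the experiment as a block, 19 probes were higher and 13 lower in GRβ larvae, among them LOL03948 (difference 1.44, limma adjusted p = 0.00406) and A_15_P101987 (difference -0.90, limma adjusted p = 0.00789). In simulated arrays, the unblocked test recovered 97% of 4-fold, 80.6% of 2-fold and 31.3% of 1.5-fold differences. Their noise was independent between arrays, and they held planted 4-fold changes, which ease the adjusted threshold. LOL03948, with a difference of 1.44, did not pass without the block, so these shares need not hold for the real arrays.

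Under beclomethasone, 16 probes were higher and 2 lower in GRβ than in wild type larvae (limma, 4 against 4 arrays), and 3186 had an unadjusted p below 0.05. Of the 16 higher probes, 14 are the set of overlapping or consecutively named probes described below (limma adjusted p 0.00145 to 0.0118). The 18 passing probes fall into 10 families of overlapping sequences, so they are not 18 separate observations. With the experiment as a block, 18 were higher and 6 lower, and 11836 had an unadjusted p below 0.05. A share of 0.05 of the tested probes, which chance alone gives on average, lies between 3186 and 11836. The largest rises were those of LOL03949 (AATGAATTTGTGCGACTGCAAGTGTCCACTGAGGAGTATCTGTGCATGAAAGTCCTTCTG), 2.02 log2 units (SE 0.20, limma adjusted p = 0.00145) and a 4.06-fold difference, and of LOL03948, 2.02 (SE 0.21, limma adjusted p = 0.00145), each in 4 of 4 experiments. The lower probes were A_15_P101987, with a difference of -0.91 (SE 0.12, limma adjusted p = 0.0116), and MAD_Dr_004_190886-1 (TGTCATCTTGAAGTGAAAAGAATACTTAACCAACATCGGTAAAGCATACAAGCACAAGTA), with -0.73 (SE 0.11, limma adjusted p = 0.0368). Each lay lower in 4 of 4 experiments, which, as for the rises, the rule for naming probes fixed beforehand. Both missed the threshold when only the groups compared were fitted and when Cy3 was used alone. MAD_Dr_004_190886-1 also missed it under 3 other settings and without any 1 of the 8 arrays, and A_15_P101987 without any 1 of 4 of those arrays.

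Over both treatments, 24 probes were higher and 13 lower in GRβ larvae (limma, 8 against 8 arrays), and 4989 had an unadjusted p below 0.05. LOL03948 was higher by 1.73 log2 units (SE 0.15, limma adjusted p = 0.000102) and LOL03941, which has the sequence of LOL03949, by 1.69 (SE 0.15, limma adjusted p = 0.000111). MAD_Dr_004_136142-1 (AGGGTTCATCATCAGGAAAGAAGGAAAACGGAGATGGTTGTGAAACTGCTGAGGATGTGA) was lower, with a difference of -1.74 (SE 0.20, limma adjusted p = 0.0016), and so was A_15_P101987, with -0.91 (SE 0.09, limma adjusted p = 0.000162). By the rule for naming probes, the 8 arrays of one genotype all lay above the 8 of the other for each of these 4 probes. With the experiment as a block, 88 probes were higher and 67 lower, and 20042 had an unadjusted p below 0.05. A share of 0.05 of the tested probes, which chance alone gives on average, lies between 4989 and 20042. Both fits count the vehicle and beclomethasone arrays of one genotype and experiment as independent. Genotype differences of one experiment correlated across the treatments (mean r = 0.193, against 0.078 between experiments). The standard errors and adjusted p-values over both treatments may therefore be too small.

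Of the 24 higher probes, 14 formed a set singled out after its values were seen. They have consecutive names or sequences that overlap those of consecutively named probes, and they fall into 6 families of overlapping sequences with at least 2 probes each. Over both treatments they were higher in GRβ larvae by 1.01 to 1.73 log2 units. Their mean was higher by 1.24 ± 0.43 (SD, n = 4 experiments) under vehicle, a 2.36-fold difference, and by 1.80 ± 0.33 (SD, n = 4 experiments) under beclomethasone, a 3.49-fold difference. The difference was larger under beclomethasone in 4 of 4 experiments, by 0.57 log2 units on average (0.34 to 0.76). An exact two-sided sign-flip test of the 4 paired values gave p = 0.125, the smallest that 4 pairs allow, so that it could not pass 0.05. The genotype difference itself gave an exact permutation p of 0.0286 under each treatment, the smallest possible, but this test is void, because the probes were chosen for that difference on the same arrays. The run of names holds 16 probes, 12 of which belong to the set, and the other 4 differed by 0.01 log2 units between the genotypes.

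**Figure D4:**
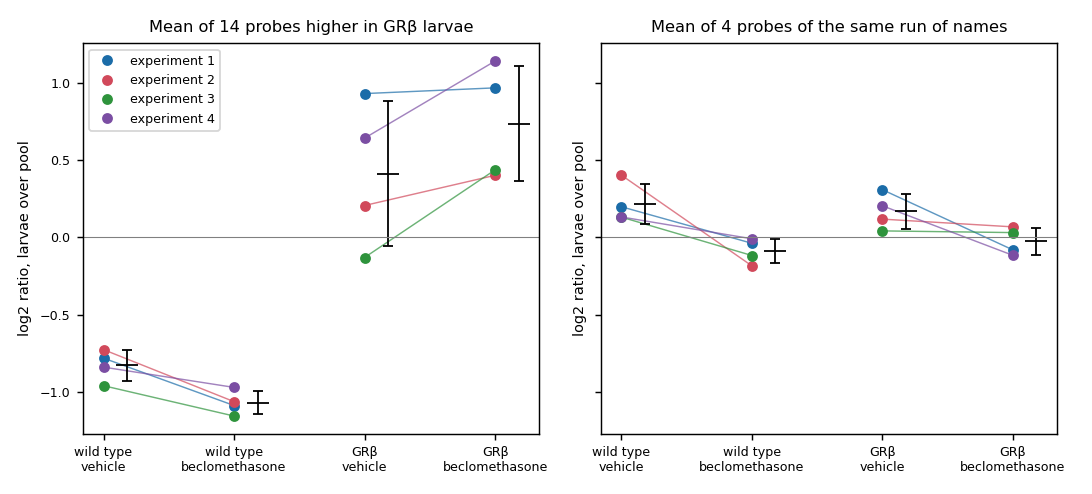
Mean log2 ratio of larvae over the common reference (y axis) in the 4 groups (x axis) for the 14 probes higher in GRβ larvae (left) and for the 4 probes of the same run of names that did not differ by the test (right). Points are arrays coloured by experiment, lines join arrays of one genotype and experiment, and bars give the mean ± SD of 4 arrays; on the left every GRβ array lies above every wild type array.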

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

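The tests of the dyes, of a sequence variant and of an added transcript were chosen only after the result was seen, and the tests of neighbouring spots and of correlations between experiments before.

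In 4 of 62 groups of 4 arrays, 1 array lay far from the other 3, where chance marks about 5% of groups. Replicate 3 of GRβ with beclomethasone had -1.55 for MAD_Dr_004_711827-1, against -1.82 to -1.77. Replicate 1 of GRβ with vehicle had -0.25 for MAD_Dr_004_190886-1, against 0.10 to 0.12, and -2.25 for MAD_Dr_004_136142-1, against -1.05 to -0.96. Replicate 2 of wild type with vehicle had -0.85 for LOL03948, against -1.04 to -1.01.

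The changes under treatment lay in the channel that the labels give to the common reference. If the dyes ran as labelled, and without a dye bias at single probes, no probe would have a mean Cy5/Cy3 ratio above 2 over the 16 arrays. The pool would hold the mean of the samples, but 511 probes lay above 2. Dyes were not swapped, so a dye bias at single probes could not be measured. If they ran the opposite way, Cy3 alone would carry the differences under beclomethasone, and it gave 13237 probes for beclomethasone over both genotypes against 3 for Cy5 alone. These counts are the pattern itself, so they are no separate test of it. Other counts were small and went either way: Cy5 alone gave 7 probes for GRβ under vehicle and 4 for the interaction, where Cy3 alone gave 0. Cy3 alone gave 36 probes for GRβ over both treatments and 16 for GRβ under beclomethasone, where Cy5 alone gave 0. A dye assignment opposite to the labels, the same on all 16 arrays, is the likely reading. No biological explanation was tested for this pattern.

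The set of 14 probes that was higher in GRβ larvae drew 4 explanations, of which 3 were tested. A local defect of the array surface argues for a shift in the surrounding spots as well, but the median difference of 162 neighbouring spots was 0.01 log2 units (0.011), against 1.62 for the set. A single sequence variant under a probe could raise 1 family of overlapping probes, and 6 families rose by more than 1 log2 unit. An added transcript in GRβ larvae, such as that of the construct, that holds the sequences of the set but not those of the 4 unchanged probes of the run, and a difference between the fish strains in the level of a transcript, cannot be told apart here. The mean difference under beclomethasone was -0.24 ± 0.10 log2 units for the set and -0.30 ± 0.20 for the 4 probes in wild type larvae (SD, n = 4), which lack the construct, a difference of 0.06 with an SD of 0.136 over the experiments. In GRβ larvae it was 0.32 ± 0.25 for the set and -0.19 ± 0.19 for the 4 probes (SD, n = 4). These changes were not tested for the set as a whole, and its named probes did not pass for beclomethasone in either genotype (LOL03948, limma adjusted p = 0.789 in wild type and 0.568 in GRβ larvae). The wild type values would be the same under both explanations, so they decide nothing between them, and the files name no gene.

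Differences between GRβ and wild type larvae resembled each other under the 2 treatments (r = 0.397 across probes), although no array is shared. If larvae of one genotype and experiment shared a clutch or handling, the resemblance would be found within experiments, and if GRβ had a common effect, between experiments too. The mean correlation was 0.193 within experiments and 0.078 between them, a quotient of 0.406, but the quotient ran from 0.173 to 0.988 when 1 experiment was left out. The explanations cannot be told apart with 4 experiments.

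Other splits of the arrays were counted as a test of chance. Of the 35 splits of the 8 wild type arrays, 1 (the real one) gave 5776 probes for beclomethasone and the highest other gave 0. For beclomethasone in GRβ larvae 1 of 35 gave 5501 and the highest other 376, and for GRβ under beclomethasone 1 of 35 gave 18 and the highest other 4. The experiments pair the arrays, and of the 35 splits in each of these comparisons 8 part every pair, as the real one does. The highest other among them was 0 in each comparison, and 8 splits are too few for a share below 0.05.

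Over both genotypes 1 of 100 splits gave 12936 probes for beclomethasone and the highest other 6759. Among 100 splits that part every pair, 1 gave as many and the highest other was 2442. For GRβ over both treatments 2 of 100 splits gave 37 or more. The highest other, 9695, set all arrays of experiments 2 and 3 against those of experiments 1 and 4, which points to a structure of the samples by experiment. With the experiment as a block 155 probes passed. Among 100 splits that part every pair, 1 gave as many as 37 and the highest other was 1. In both comparisons chance was excluded only if the 2 pairs of an experiment are independent of each other, because these splits exchange them separately. Exchanged by whole experiments there are 8 splits, too few for a share below 0.05. For GRβ under vehicle (0 probes, 35 of 35 splits as large, highest other 0) and for the interaction (0 probes, 100 of 100, highest other 83), a count of 0 makes every split as large, so that the splits say nothing about chance.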

How the results depend on the processing

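The filter on Cy3, Cy3 alone and the mean per probe family were chosen after seeing the data. Of 74 counts under settings other than leaving out arrays, 64 stayed within 1.5 times the reported one. The experiment as a block (the pairing) gave 14680 probes for beclomethasone in wild type, 14581 in GRβ larvae, 26471 over both genotypes, 32 for GRβ under vehicle and 155 for GRβ over both treatments. It gave 24 in place of 18 for GRβ under beclomethasone and 0 for the interaction. Of the named probes, it passed A_15_P101987, LOL03948, LOL03949, LOL03941 and MAD_Dr_004_136142-1 (limma adjusted p 0.0275 in place of 0.104) under vehicle and MAD_Dr_004_691088-1 for beclomethasone in GRβ larvae (0.0387 in place of 0.0807), and it changed no other call of a named probe. The block removes the differences between experiments from the spread, which explained 98.4% of the first principal component. A limit of 1.5-fold, which by construction passes fewer probes, gave 3404, 3198 and 3733 for beclomethasone in wild type, in GRβ larvae and over both genotypes. The mean per family, with fewer values tested, gave 9 for GRβ under beclomethasone and 23 for GRβ over both treatments. The interaction count was 0 under the settings run on ratios and with Cy3 alone, and so was GRβ under vehicle except with the block and without 1 array. Cy5 alone, read here as the reference, gave 4 and 7.

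Leaving out 1 array gave 3981 to 5370 probes for beclomethasone in wild type, 3632 to 5537 in GRβ larvae, 11029 to 13024 over both genotypes, 0 to 9 for GRβ under vehicle, 13 to 18 under beclomethasone, 26 to 33 over both treatments and 0 to 0 for the interaction. Replicate 3 of GRβ with vehicle decided the extremes 3632 and 9. The difference of the response scores, -0.008, ran from -0.033 to 0.032 without 1 array. It turned positive without GRβ vehicle replicate 1 (0.013) or 4 (0.019), GRβ beclomethasone replicate 1 (0.010) or 4 (0.032), or wild type vehicle replicate 2 (0.003). The exact permutation p was 0.314 to 1 without 1 array, and the no replicate block test gave -0.008 (exact permutation p = 0.812). Of 230 values of named probes under the other settings, 221 kept direction and side of the threshold, 7 lost the threshold, 2 gained it and 0 turned; of 272 without 1 array, 12 lost it and 1 gained it. Sizes moved more than calls: with Feature Extraction's processed signals MAD_Dr_004_157486-1 rose by 5.62 over both genotypes in place of 4.20 and MAD_Dr_004_163333-1 by 5.61 in place of 4.90, so that the order of the 2 largest rises named turned, and MAD_Dr_004_196898-1 differed by -3.54 in place of -2.61. The losses were those of 2 probes in GRβ against wild type under beclomethasone. Both fell short with only the groups compared (limma adjusted p 0.0841 and 0.0884) and with Cy3 alone (0.118 and 0.136), and MAD_Dr_004_190886-1 also with Feature Extraction's processed signals (0.085), the intensity trend with robust prior (0.0604) and the mean per family (0.0592). Without 1 array they were MAD_Dr_004_190886-1 without any 1 of the 8 arrays compared (limma adjusted p 0.103 to 0.231), and A_15_P101987 without replicate 1 or 4 of either group (0.0617 to 0.0732). The gain was that of LOL03948 under vehicle without replicate 3 of GRβ with vehicle (limma adjusted p = 0.0105). Quantile normalisation between arrays leaves ratios as they are, so it tests nothing and is left out of the counts of settings given here. Not run were the series value table, which holds errors, and all summaries and tests by gene (means per gene name, the list of receptor targets, gene list tests with their alternatives), since no probe has a gene name. Dim probes limit what can be seen: 39262 were not well above background in Cy5, read here as the reference, on all arrays of any group. The same filter on Cy3 kept 140640 probes in place of 136712.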

Other observations

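The tests in this part were not planned. The probes of the run that did not differ between genotypes, with the probes that overlap them, responded to beclomethasone: all 9 fell over both genotypes (limma, adjusted p below 0.05), for example MAD_Dr_004_154664-1 (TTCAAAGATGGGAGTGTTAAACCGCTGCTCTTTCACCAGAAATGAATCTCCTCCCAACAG) by -0.24 log2 units (limma adjusted p = 0.0222). These probes overlap or repeat one another's sequences within few families, so they are not 9 separate observations. The mean of the 4 run probes fell in 8 of 8 pairs of one genotype and experiment, by 0.25 ± 0.19 (SD). The mean of the set of 14 probes differed by -0.24 ± 0.10 under beclomethasone in wild type and by 0.32 ± 0.25 in GRβ larvae (SD, n = 4 experiments), and these changes of the set were not tested.

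Some transcribed regions carry probes for both strands. Among 1289 pairs of probes with opposite-strand sequences, the beclomethasone differences over both genotypes correlated with r = 0.849 across pairs. Both strands passed in 92 pairs, where independent strands would give 14.8, and the direction was the same in 92 of them and opposite in 0. Probes that repeat a sequence at another place of the array correlated with r = 0.969 for beclomethasone over both genotypes and 0.93 for GRβ over both treatments, across 1165 pairs.

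Arrays differed most by experiment. The first principal component held 28.6% of the variance, of which experiment explained 98.4% and treatment 0.1%. The second held 22.8%, of which treatment explained 77.9%. Genotype explained 0.1% of the first, 3.2% of the second, 8.9% of the third and 11.7% of the fourth.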
